A study of Oncorhynchus mykiss with 28 samples.

How the data were processed

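Libraries were made from 800 ng of pooled RNA per sample by poly(A) selection with a stranded kit and sequenced on a NextSeq500 with paired reads. The submitters' processing notes give Salmon 1.2.1 as the quantification tool. Each file lists 78931 transcripts. As deposited, the estimated counts (expected counts) are the reads that the submitters' Salmon run assigned to each transcript, not scaled for depth or length, and they were rounded to whole counts here. As deposited, the TPM values were scaled by Salmon for effective length and depth and were not tested here. Effective lengths, also from the submitters' Salmon run, served as offset and bias score. The build of the transcript set and the salmon settings are not stated. One protocol text gives 45 days for the early sampling while titles, characteristics and design give 5, and 5 was used.

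Transcript accessions were matched without their version to a table of genes of the assembly USDA_OmykA_1.1. This placed 42376 transcripts (53.7%, with 65.1% of reads) in 25115 genes, and 12034 transcripts (23.4% of reads) carried a symbol that is not a locus number. With so many transcripts unmatched, transcripts were tested and counts summed by gene served as an alternative. Counts of 1 transcript can shift to another of the same gene, or between paralogs of the duplicated salmonid genome, so the fold change of the gene is given beside single transcripts whose gene did not share the change. No genome positions were used here, and symbols come from the table, with no description of function.

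Transcripts were kept by edgeR's filterByExpr with a minimum count of 10 and total of 15 (46046 transcripts, 99.7% of reads; 18068 genes in the alternative). Libraries were normalised by TMM, 1 quasi-likelihood model with 8 group means was fitted to all 28 libraries, and contrasts were tested by edgeR with 2-sided p-values, with Benjamini-Hochberg adjustment over all transcripts of a contrast and a threshold of 0.05. The model had 20 residual degrees of freedom and a common dispersion of 0.65 (0.064 for genes). The unit of replication was the pool. P-values therefore measure the spread between pools, and where a sham group or Commercial infected fish at 21 dpc came from 1 tank they do not cover differences between tanks. A group left with 1 pool is assumed to vary like the other groups. CPM are counts per 1000000 with TMM scaling; "gene value" is the log2 fold change of counts summed by gene. The tests used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

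Infection was compared with sham per strain and day, strains per day and treatment, days per strain and treatment, the strain by infection interaction per day, and time by infection in Select fish. These 15 contrasts, the filters, the model, the 27 gene lists and the rule for named genes were set before the data were examined. The rule names the 8 highest and 8 lowest log2 fold changes among called transcripts with a symbol and at least 2 CPM on average, and up to 4 called members of each called list. The text gives these from the top of each order, and some that the rule names are left out. Genes singled out beyond it, such as those of Select fish at 21 dpc with counts summed by gene or without 1 pool, were chosen after their values were seen. For counts of 5 or fewer all symbols are named.

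Lists were tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists of a contrast. Of the 27 lists 25 had at least 2 tested transcripts, while MHC class II presentation and mitochondrially encoded genes had too few to be tested, and 7 symbols were removed as wrong matches. The lists cover immune proteins (acute phase, cytokines, complement, interferon, MHC), blood and immune cell markers, cell types of the gut wall, other organs that a dissection can include (pancreas, liver, skeletal muscle), and cell division, stress, lipid, junction, matrix and ribosome genes. Medians with 0-count transcripts at their bound were equal to 2 decimals except where both are given.

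A group at 0 counts was given a floor of 3 counts over the group, and fold changes against it are written as "at least". With 1 to 3 counts a ratio with its 95% counting interval is given. Floors and intervals cover counting error only, since reads are not independent molecules. A library bias score, the first component of log effective lengths (84.3% of their variance), was added after the data were seen, as a covariate and by its sign. Counts were also simulated from 1 mean level per transcript and the dispersions and library sizes of these data. Known changes were put into transcripts of at least 2 CPM, and differences between tanks or in library bias were not simulated. There edgeR recovered 20%, 74%, 76% and 88% of transcripts changed 2-fold, 4-fold, 8-fold and 16-fold in the design of Select fish at 5 dpc. In that of Commercial fish at 21 dpc it recovered 8%, 46%, 70% and 58%. For the interaction at 5 dpc, with changes in infected Select fish alone, it recovered 6%, 32%, 62% and 66%.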

Results

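RNA was sequenced from the whole intestine of all-female rainbow trout of 2 strains that had been reared together from the egg. Select is a selected strain that the series title credits with better growth and immune performance, and Commercial is a farmed strain that served as its reference. Fish were injected intramuscularly with Flavobacterium psychrophilum, the cause of bacterial cold water disease, or received a sham injection, and intestines were taken at 5 and 21 days post challenge (dpc). Each library held poly(A) RNA pooled from 2 fish of 1 tank. Each strain had 3 infected tanks (CF1 to CF3 for Select, TF1 to TF3 for Commercial) and 1 sham tank (CFC and TFC), with 2 pools per tank and day, written CF1-1 and CF1-2. The 28 libraries formed 8 groups of 6 infected or 2 sham pools, except that Commercial infected fish at 21 dpc were sampled from tank TF1 alone, with 2 pools, after high mortality. Sham fish of a strain came from 1 tank, so a difference between infected and sham fish is also a difference between tanks.

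Estimated counts per library, in units of 1000000, ran from 6.06 to 17.667 with a median of 7.57. Of 78931 transcripts, 46046 had enough counts to be tested, and 8487 of these carried a gene symbol. On the first principal component (11.2% of variance) the 12 infected pools of 5 dpc had scores from -100.1 to -68.5, and the other 16 libraries had scores from 0.6 to 131.8. On the second (6.2%) Select pools had scores from 14.8 to 83.7 and Commercial pools from -100.5 to -45.2. Pearson's r of log2 counts per 1000000 counts (CPM) between 2 libraries, across transcripts, lay between 0.766 and 0.856.

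**Figure D1:**
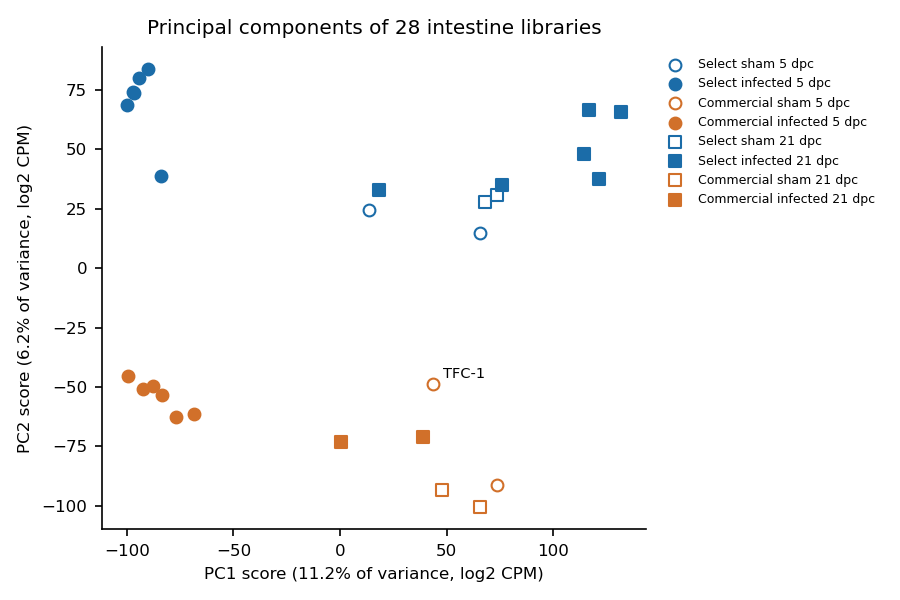
Score of each library on the first (x axis) and second (y axis) principal component of log2 CPM, in arbitrary units; 1 point is 1 library, with colour and shape giving strain, infection and day. The 12 infected pools of 5 dpc have x scores of -68.5 or less, and all others of 0.6 or more.

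The first comparison asked what infection changed in the intestine of Select fish at 5 dpc, with 6 infected against 2 sham pools. Transcripts of inflammation, complement, interferon response and antigen presentation were higher in infected fish, and those of cell division and fatty acid oxidation were lower. The acute-phase protein serum amyloid A (saa, NM_001124436.1) averaged 353 ± 55.2 CPM (SD, n = 6) in infected fish and 0.322 ± 0.0303 CPM (n = 2) in sham fish, a 1030-fold rise (adjusted p = 0.000143). The chemokine ccl19a.1 (XM_021605155.1), which guides T cells and dendritic cells, rose 329-fold from 0.909 ± 0.00991 to 305 ± 61.4 CPM (adjusted p = 8.54e-05). The itaconate-making enzyme of activated macrophages, acod1, reached 36.9 ± 6.2 CPM over 3 sham counts, a ratio of 337 with a counting interval of 115 to 1630 (adjusted p = 9.92e-06). The B cell chemokine cxcl13 and the cytokines il10 and ifng had no sham count and were at least 28.7-fold, 12.8-fold and 11.6-fold higher. Among the largest decreases, plvapb (XM_021604712.1), which forms the diaphragms of fenestrated endothelium, fell 13.5-fold from 46.9 ± 2.56 to 3.47 ± 1.07 CPM (adjusted p = 4.5e-06). The citrate transporter slc13a5b fell 8.93-fold (adjusted p = 7.87e-06). The channel-like protein pkd1l2a fell 26.5-fold (adjusted p = 0.000518; gene value -3.94) and cyp1a3, which oxidises foreign compounds, 8.26-fold. A single transcript of nmd3 was at least 43.2-fold higher and 1 of mfn2 was 14.4-fold lower, while their genes had log2 fold changes of 0.60 and -0.75. Of these transcripts, each lay beyond both sham pools in all 6 infected pools, except cyp1a3 (5 of 6). By edgeR, 1352 transcripts were higher and 1608 lower, 655 of them with a symbol, and 8261 had an unadjusted p under 0.05 where 2302 would by chance. Without sham pool CFC-2 the total was 688 and 23 of the 37 named calls of this comparison were lost (adjusted p 0.0637 to 0.764), with cyp1a3 at a log2 fold change of -1.24 in place of -3.05. Of these calls, 8 were lost without CFC-1 (0.0507 to 0.224) and that of cyp1a3 without CF3-2 (0.0526). The 14 that held in every such fit were those of saa, ccl19a.1, acod1, cxcl13, c7b, stat1b, tap1, gcg2, plvapb, slc13a5b, pkd1l2a, defb3, anpepa and top2a.

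The gene lists fixed before the data were examined showed the same groups in Select fish at 5 dpc. Interferon-induced genes had a median log2 fold change of 2.51, and 8 of 19 transcripts rose (14 adjusted over the list alone; adjusted p = 3.14e-11 by camera and adjusted p = 0.0112 with an estimated correlation). The signal transducer stat1b rose 9.46-fold, the antiviral GTPase mx 8.2-fold and the transcription factor irf1b 8.06-fold. Of 9 transcripts of MHC class I presentation, 3 rose (7 adjusted over the list alone; adjusted p = 6.57e-10, and adjusted p = 0.0112 with an estimated correlation). The peptide transporter tap1 (XM_021559784.1) went from 41.2 ± 4.75 CPM in sham fish to 139 ± 23.1 (3.37-fold, adjusted p = 9.82e-06, all 6 pools). The immunoproteasome subunit psmb8a rose 2.15-fold and the transporter subunit tap2t 1.63-fold. Complement rose in 4 of 10 transcripts (5 adjusted over the list alone; median 2.08; adjusted p = 1.35e-06, and adjusted p = 0.0349 with an estimated correlation). Component c4b rose 45.2-fold, the pore-forming c7b 31.3-fold to 150 ± 29.9 CPM and the regulator cfh 9.97-fold. Acute phase and antimicrobial proteins rose in 3 of 5 transcripts and fell in 1 (4 and 1 adjusted over the list alone; median 2.36; adjusted p = 0.000744, and adjusted p = 0.0155 with an estimated correlation). The haem-binding hpxb rose 37.0-fold, lysozyme (lyz2) rose 5.12-fold to 263 ± 36.1 CPM, and the beta-defensin defb3 fell 2.91-fold. Cytokines and chemokines rose in 4 of 16 (8 up and 1 down adjusted over the list alone; median 0.95; adjusted p = 2.06e-05, and adjusted p = 0.0159 with an estimated correlation). Cell division fell in 5 of 16 transcripts (8 adjusted over the list alone; median -1.25; adjusted p = 2.08e-07, and adjusted p = 0.0269 with an estimated correlation). The topoisomerase top2a fell 3.08-fold to 34.5 ± 7.04 CPM and birc5a, which acts in chromosome segregation, 2.8-fold. Fatty acid oxidation fell in 10 of 24 (1 up and 12 down adjusted over the list alone; median -0.75; adjusted p = 2.12e-08, and adjusted p = 0.0112 with an estimated correlation). The carnitine carrier slc25a20 fell 2.49-fold.

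Further lists in Select fish at 5 dpc were called only with the preset correlation. Brush border and absorption genes had 4 of 16 transcripts down and 1 up (5 and 2 adjusted over the list alone; adjusted p = 0.0241, but adjusted p = 0.224 with an estimated correlation). Of these, the peptidase anpepa fell 2.82-fold from 1468 ± 1.28 to 521 ± 66.2 CPM (adjusted p = 2.08e-05), the fatty acid carrier fabp2 fell 2.67-fold and the microvillus protein vil1 1.93-fold. Neutrophil and granulocyte markers had 4 of 13 transcripts up (4 adjusted over the list alone; median 0.81; adjusted p = 0.0111, but adjusted p = 0.25 with an estimated correlation). They were the matrix protease mmp9 (101-fold), the oxidase subunit ncf4 (4.2-fold) and 2 transcripts of the chemotactic factor lect2 (at least 27.9-fold and 28.8-fold). Among enteroendocrine hormones 1 of 8 rose (1 adjusted over the list alone; adjusted p = 0.0366, but adjusted p = 0.109 with an estimated correlation). It was the glucagon precursor gcg2, at 42.6 ± 5.57 against 18.1 ± 2.39 CPM (adjusted p = 0.00028, all 6 pools). Smooth muscle had 2 of 10 transcripts down (1 up and 4 down adjusted over the list alone; adjusted p = 0.00375, but adjusted p = 0.094 with an estimated correlation). These were synpo2b (5.17-fold) and smtna (2.1-fold), and the list had a median of -0.53 and a mean of 0.10. The goblet cell list held only 2 transcripts of agr2, 0 called by edgeR (2 adjusted over the list alone; adjusted p = 0.0241, but adjusted p = 0.17 with an estimated correlation). The T cell, B cell, macrophage, exocrine pancreas, liver-secreted, skeletal muscle, erythrocyte, unfolded protein response, heat shock, cholesterol biosynthesis, epithelial junction, extracellular matrix and ribosomal protein lists were not called, with adjusted p from 0.0819 to 0.933. Each named transcript here lay beyond both sham pools in all 6 infected pools, and the libraries that end calls are those given with the first genes of this comparison. Infected against sham fish gave 695 calls with pools of a tank summed, and 353 or 2410 among libraries whose bias score, a measure of salmon's effective lengths, was above 0 (2 infected pools against CFC-1) or below 0 (4 against CFC-2).

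**Figure D2:**
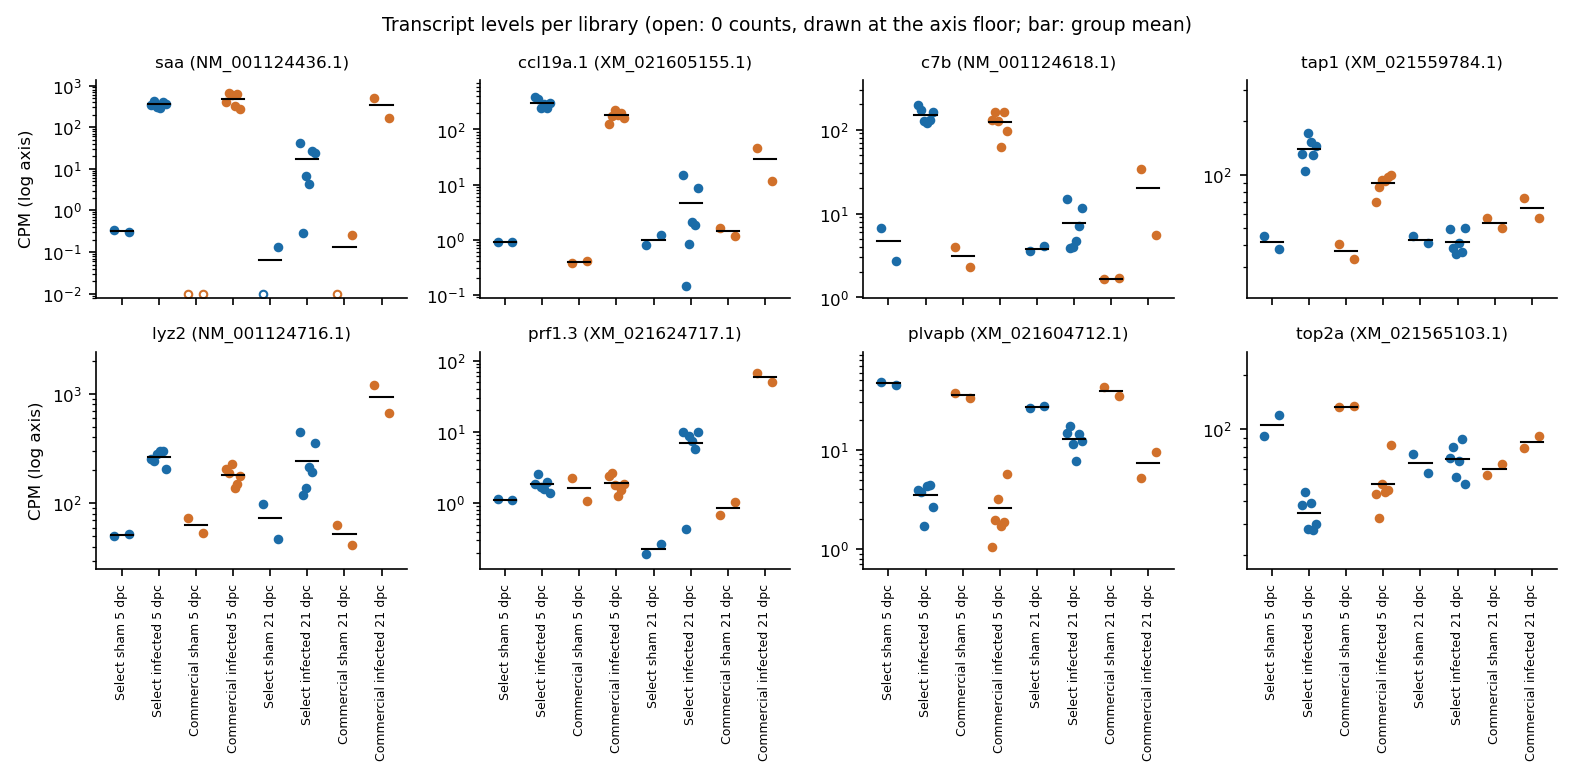
CPM of 8 transcripts (y axis, logarithmic) in each library, by strain, infection and day (x axis). Points are libraries, bars are group means, and open points mark libraries with 0 counts, drawn at the floor of the axis.

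The same question in Commercial fish at 5 dpc also set 6 infected pools against 2 sham pools, and again acute-phase transcripts were higher and cell division transcripts lower. Serum amyloid A averaged 484 ± 171 CPM in infected fish with no sham count, at least 2510-fold higher (adjusted p = 0.000122). The chemokine ccl19a.1 rose 447-fold to 180 ± 36.7 CPM (adjusted p = 0.000156), while cxcl13 rose 9.92-fold and il10 at least 5.02-fold. Acute phase and antimicrobial proteins rose in 3 of 5 transcripts (3 up and 1 down adjusted over the list alone; median 1.52; adjusted p = 0.000926, and adjusted p = 0.0336 with an estimated correlation). Among them hpxb rose 33.6-fold and lyz2 2.86-fold. Enteroendocrine hormones rose in 2 of 8 (2 adjusted over the list alone; median 1.75, or 1.61 with 0 counts at their bound; adjusted p = 0.00151, and adjusted p = 0.0336 with an estimated correlation). Glucagon precursor gcg2 was at 56.3 ± 7.6 against 19.9 ± 3.92 CPM (2.83-fold, adjusted p = 6.52e-05). Cell division fell in 8 of 16 (8 adjusted over the list alone; median -1.32; adjusted p = 8e-08, and adjusted p = 0.0336 with an estimated correlation). Topoisomerase top2a fell 2.69-fold (adjusted p = 0.000976), cdc20, an activator of mitotic exit, 5.24-fold (gene value -1.53) and birc5a 3.6-fold. The endothelial gene plvapb fell 13.4-fold from 35.3 ± 2.9 to 2.59 ± 1.7 CPM (adjusted p = 8.17e-06), and 1 of 2 bmb transcripts stood at a log2 fold change of -4.47 (gene value -2.07). Each transcript named so far lay beyond both sham pools in all 6 infected pools, as did those that follow except tbc1d10c (5 of 6), ddx24 and dhrs7. Several of the largest changes were in single transcripts: those of cd4-1, tbc1d10c, itcha, sh3d21 and zmiz2 were at least 58.4-fold, 59.5-fold, 44.1-fold, 42.1-fold and 40.1-fold higher. Their genes had log2 fold changes of 0.86, 0.06, 0.92, 1.02 and 0.05. A second cd4-1 transcript was 35.7-fold lower. Transcripts of ddx24, dhrs7 and tnr5 were at least 118-fold, 21.4-fold and 8.76-fold lower, but ddx24 and dhrs7 had counts in 1 sham pool, TFC-1, and in no other Commercial pool of 5 dpc. The gene value of ddx24 was -0.41, and dhrs7 and tnr5 had no other transcript to sum. By edgeR, 1615 transcripts were higher and 1454 lower, 647 of them with a symbol, and 8898 had an unadjusted p under 0.05. Without sham pool TFC-2 the total was 522 and without TFC-1 1152, and 25 and 19 of the 37 named calls were lost (adjusted p 0.0669 to 0.496 and 0.078 to 0.245), besides ddx24 and dhrs7, which had no count left without TFC-1. Leaving out an infected pool ended 6 calls (TF1-1), 3 (TF1-2), 9 (TF2-1), 2 (TF2-2), 6 (TF3-1) or 2 (TF3-2), with adjusted p from 0.0504 to 0.0752, and moved bmb to -8.85 (TF1-2) and the lower cd4-1 transcript from -5.16 to -9.00 (TF3-1). The calls of saa, ccl19a.1, c7b, stat1b, tap1, gcg2, itcha, plvapb and top2a held in every such fit.

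Other lists in Commercial fish at 5 dpc were called with the preset correlation and lost with the estimated one. Interferon-induced genes rose in 3 of 19 transcripts (3 adjusted over the list alone; median 0.83, or 0.81 with 0 counts at their bound; adjusted p = 0.000623, but adjusted p = 0.131 with an estimated correlation). Here stat1b rose 7.36-fold to 18.6 ± 2.38 CPM (adjusted p = 0.000368) and 2 transcripts of irf1b rose 5.8-fold and 3.92-fold. MHC class I presentation rose in 3 of 9 (5 adjusted over the list alone; adjusted p = 9.63e-05, but adjusted p = 0.08 with an estimated correlation). The transporter tap1 was at 89.5 ± 10.9 against 37 ± 5.07 CPM (2.42-fold, adjusted p = 0.000208), psmb8a rose 1.79-fold and tap2t 1.41-fold. Complement rose in 3 of 10 (6 adjusted over the list alone; median 1.04; adjusted p = 1.36e-05, but adjusted p = 0.0749 with an estimated correlation). Its members c4b, c7b and cfh rose 53.5-fold, 39.0-fold (to 123 ± 38.7 CPM, adjusted p = 0.000126) and 6.15-fold. Cytokines and chemokines had 3 of 16 up (6 up and 2 down adjusted over the list alone; adjusted p = 0.0119, but adjusted p = 0.131 with an estimated correlation). Neutrophil markers had 2 of 13 up (4 adjusted over the list alone; adjusted p = 0.0181, but adjusted p = 0.276 with an estimated correlation), mmp9 (13.7-fold) and lect2 (at least 10-fold). Erythrocyte genes had 3 of 7 down (4 adjusted over the list alone; median -1.55; adjusted p = 0.00243, but adjusted p = 0.0749 with an estimated correlation). The globins hba1, hbb1 and hba4 fell 3.29-fold, 3.36-fold and 2.92-fold. Skeletal muscle had 1 of 9 down (4 adjusted over the list alone; adjusted p = 0.011, but adjusted p = 0.105 with an estimated correlation). Smooth muscle had 3 of 10 down, synpo2b by 3.02-fold among them, with a median of -0.60 and a mean of 1.09 (4 adjusted over the list alone; adjusted p = 0.00804, but adjusted p = 0.131 with an estimated correlation). In the unfolded protein response 1 of 16 was lower, the chaperone calr (3.04-fold; 2 adjusted over the list alone; adjusted p = 0.0268, but adjusted p = 0.433 with an estimated correlation). The goblet cell list (adjusted p = 0.0275) and fatty acid oxidation (median -0.26; adjusted p = 0.0181) had no called member by edgeR (adjusted p = 0.213 each with an estimated correlation). Ribosomal proteins were called in this and 8 other comparisons with the preset correlation and in none with the estimated one (here adjusted p = 0.323). Losses of named calls are counted with the first genes of this comparison. With pools of a tank summed there were 629 calls, and 522 among libraries with a bias score above 0, where TF1-2 was the only infected pool.

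Whether the 2 strains differed in their response at 5 dpc was tested as the interaction, the change in Select fish minus that in Commercial fish. It had 8 calls, 4 higher and 4 lower, and 2364 transcripts had an unadjusted p under 0.05 where 2302 would by chance. The only one with a symbol was the ubiquitin ligase itcha (log2 difference -8.40 ± 1.38 SE, adjusted p = 0.0277), a single transcript with counts in all 12 infected pools, in both Select sham pools and in neither Commercial sham pool, whose gene had a value of -0.81. The interferon list was higher in Select with the preset correlation (0 of 19 called by edgeR and 0 adjusted over the list alone; median 0.99; adjusted p = 0.000251, but adjusted p = 0.199 with an estimated correlation). So were MHC class I presentation (adjusted p = 0.39 with an estimated correlation), skeletal muscle (0.102), erythrocyte genes (0.199) and the unfolded protein response (0.596). Brush border genes and fatty acid oxidation were lower with the preset correlation (adjusted p = 0.199 each with an estimated correlation). The itcha call was lost without TFC-1 (adjusted p = 0.145), TFC-2 (0.154), CFC-1 (0.117), CF1-1 (0.054), CF2-1 (0.053) or CF3-1 (0.0523), and the count was 46 without TFC-1, 38 without TFC-2, 15 without CFC-1 and 16 without CFC-2. The 2 lists of calls, which share no library, had 849 transcripts higher in both where 47.4 would by chance, 738 lower in both against 50.8, and 0 called in opposite directions. A response that 1 strain passed and the other did not is therefore not shown to differ between them. Nor are the responses shown to be alike. In simulated counts the interaction test recovered 6% of 2-fold and 32% of 4-fold changes, so most differences of that size would be missed.

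At 21 dpc the response of Select fish (6 against 2 pools) was small in the transcript test. The cytotoxic pore protein perforin (prf1.3, XM_021624717.1) rose 29.2-fold from 0.23 ± 0.0481 to 7.07 ± 3.64 CPM in all 6 pools (adjusted p = 0.0219) and was the only called transcript with a symbol among 8 higher and 14 lower. In total 6105 transcripts had an unadjusted p under 0.05. With counts summed by gene, 331 genes were higher and 234 lower. Among them saa had a log2 fold change of 7.91 (adjusted p = 0.0214), acod1 of 4.80 (0.0238), c4b of 3.92 (0.0454), the hatching-enzyme-like protease hce23 of 3.86 (0.0333) and the complement receptor c5ar of 2.45 (0.0491). The globins hba1 and hbb1 were at -1.51. All 6 infected pools lay beyond both sham pools for these genes except c4b (5 above and 1 below both) and hce23 (5 above). Acute phase and antimicrobial proteins (0 of 5 called by edgeR, 3 adjusted over the list alone; median 1.19) had adjusted p = 0.00179, but adjusted p = 0.0529 with an estimated correlation. No list was called with an estimated correlation. With the preset one, neutrophil markers (6 of 13 up adjusted over the list alone), cholesterol biosynthesis, the unfolded protein response and complement were higher, and smooth muscle, exocrine pancreas, erythrocyte and interferon-induced genes were lower (adjusted p = 0.402 to 0.428 each with an estimated correlation). The prf1.3 call was lost without CF2-2 (adjusted p = 0.0534), CFC-1 (0.288) or CFC-2 (0.123). Single pools moved the count: it was 2098 without CF1-1, 105 without CF1-2, 11 without CF2-1, 4 without CF2-2, 9 without CF3-1 and 7 without CF3-2, and without tank CF1 it was 2365. In the fit without CF1-1, saa (log2 fold change 7.42, adjusted p = 0.0121), cxcl13 (4.99, 0.0158), prf1.3 and acod1 (4.38, 0.00959) passed as higher. The muscle-wasting ligase fbxo32 (-2.56, 0.0207) and the transcript of gbp (-2.45, 0.00381) passed as lower, against -0.37 (0.964) and -1.53 (0.259) with all libraries.

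In Commercial fish at 21 dpc, 2 infected pools of tank TF1 were set against 2 sham pools, and acute-phase, neutrophil and lysozyme transcripts were higher while globins were lower. Serum amyloid A was at 337 ± 240 CPM (n = 2) over 2 sham counts, a ratio of 2370 with a counting interval of 657 to 19600 (adjusted p = 0.00109). Lysozyme (lyz2) rose by a log2 fold change of 4.15 from 52.6 ± 15.6 to 933 ± 386 CPM (adjusted p = 0.000341), and acod1 was at least 61.2-fold higher (adjusted p = 0.000399). The ratios of c4b and cxcl13 were 2030 (365 to 80400) and 89.1 (15.6 to 3560). Acute phase and antimicrobial proteins rose in 2 of 5 (2 adjusted over the list alone; median 1.25; adjusted p = 0.000138, and adjusted p = 0.0158 with an estimated correlation). Neutrophil markers rose in 5 of 13 (7 adjusted over the list alone; median 2.81, or 2.49 with 0 counts at their bound; adjusted p = 9.43e-09, and adjusted p = 0.0352 with an estimated correlation). The granulocyte growth factor receptor csf3r rose 20.4-fold (gene value 3.16), ncf4 13.5-fold, mmp9 37.8-fold and lect2 at least 21.4-fold. Erythrocyte genes fell in 2 of 7 (3 adjusted over the list alone; median -2.51; adjusted p = 0.000728, and adjusted p = 0.0397 with an estimated correlation), hba1 by 9.84-fold and hbb1 by 5.68-fold. Complement had 2 of 10 up, c7b by 11.7-fold (3 adjusted over the list alone; adjusted p = 0.000193, but adjusted p = 0.126 with an estimated correlation). The B cell receptor subunit cd79b rose 7.44-fold as 1 of 7 B cell markers (1 adjusted over the list alone; adjusted p = 0.0263, but adjusted p = 0.0915 with an estimated correlation). Brush border and absorption genes had 2 of 16 down (1 up and 3 down adjusted over the list alone; adjusted p = 0.00195, but adjusted p = 0.126 with an estimated correlation). These were the vitamin receptor cubn (3.39-fold) and the glutathione-degrading ggt1b (1.82-fold), and the citrate transporter slc13a5b was 6.91-fold lower. Cytokines (adjusted p = 0.278), the unfolded protein response (0.464) and extracellular matrix (0.265; median -0.48 and mean 0.03) were called only with the preset correlation and missed with an estimated correlation. Transcripts of tmm85 and malt2 were at least 71.6-fold and 60.6-fold higher with gene values of 0.53 and 1.17. Those of znf740b, capn1, pfkfb2a and mtss1lb were at least 66.8-fold, 45.7-fold, 32.3-fold and 28.7-fold lower with gene values of -0.52, -0.17, -0.23 and 0.24. All named transcripts lay beyond both sham pools in both infected pools. By edgeR, 430 were higher and 285 lower, 135 of them with a symbol, and 5306 had an unadjusted p under 0.05. The total was 163 without TF1-1 and 171 and 410 without sham pools TFC-1 and TFC-2. Of the 22 named calls, 15 were lost without TF1-1 (adjusted p 0.0565 to 0.636, with c7b at 1.70 in place of 3.55), 7 without TF1-2 (0.0712 to 0.2), 14 without TFC-1 (0.0638 to 0.329) and 8 without TFC-2 (0.0875 to 0.293). Those of saa, acod1, lyz2, tmm85 and malt2 held in all 4 fits. With only these 4 libraries fitted edgeR called 0, and 200 were called with pools of a tank summed.

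**Figure D3:**
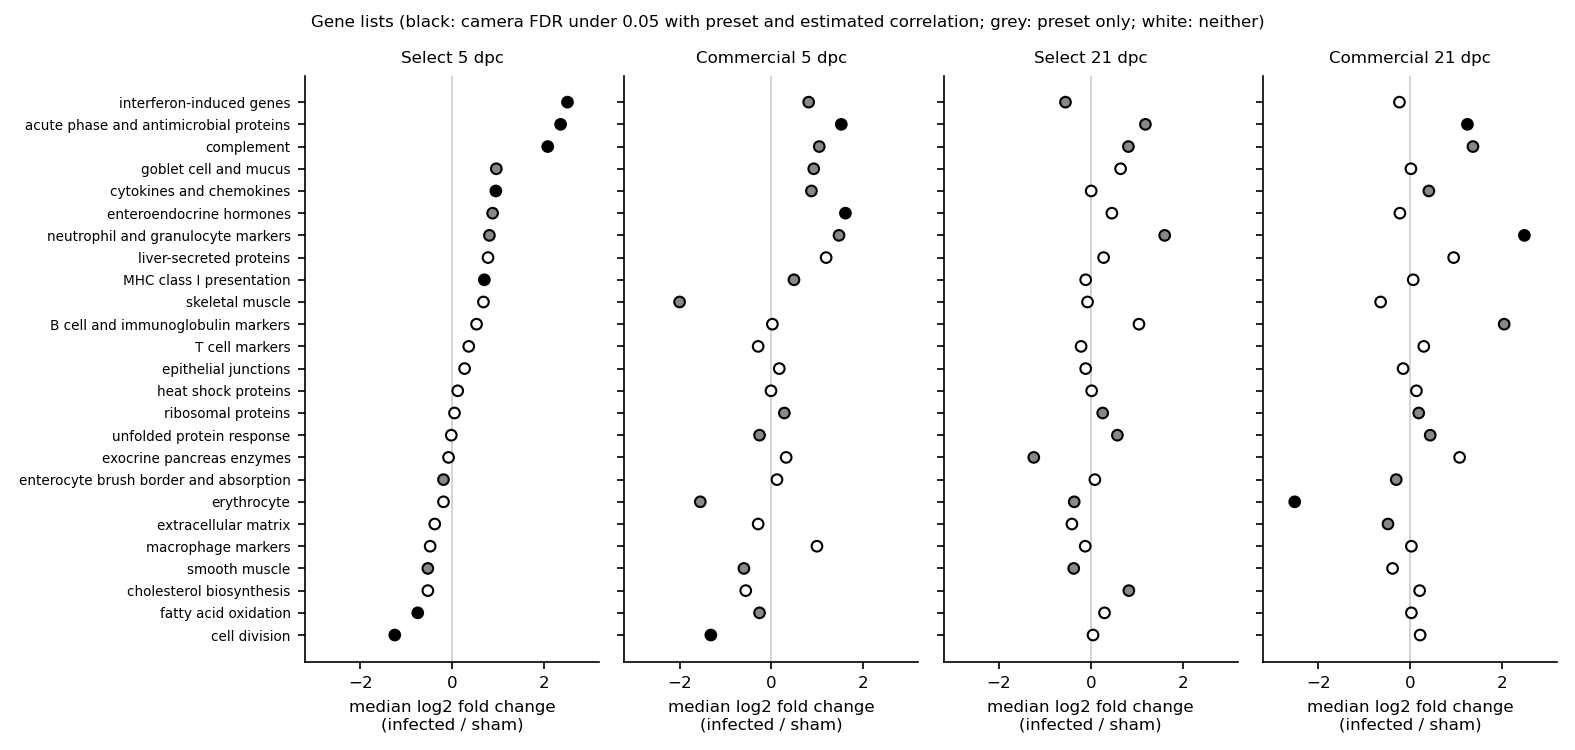
Median log2 fold change of infected against sham fish (x axis, 0-count transcripts at their bound) for 25 gene lists (y axis) in each strain and day. Each point is 1 list; black points were called with both correlations, grey with the preset one and white with neither.

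The interaction at 21 dpc (Select minus Commercial response) had 3 calls higher and 7 lower, and 3178 transcripts had an unadjusted p under 0.05. Those with a symbol were single transcripts of tmm85 (-9.58, adjusted p = 0.00128), malt2 (-9.41, adjusted p = 0.000307) and c1h19orf44 (-7.33, adjusted p = 0.0098). For tmm85 and malt2 the Commercial sham pools of 21 dpc had 0 counts and every other library had counts, and the 3 genes had values of -0.29, -0.87 and 0.45. Brush border and absorption genes were higher (median 0.48; adjusted p = 0.21 with an estimated correlation), and complement, neutrophil markers and exocrine pancreas enzymes lower (adjusted p = 0.529 each with an estimated correlation), with the preset correlation only and no called member. The call of c1h19orf44 was lost without TFC-1 (adjusted p = 0.0659) or TFC-2 (0.0749), and the count was 37 without TF1-1, 87 without TF1-2, 52 without TFC-1, 44 without TFC-2, 32 without CF1-1, 33 without CFC-1 and 25 without CFC-2.

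A direct comparison of infected fish at 5 dpc asked how the strains differed while infected, with 6 pools of 3 tanks on each side. Interferon-induced and antigen presentation transcripts were higher in Select fish and liver-type secreted proteins were higher in Commercial fish. Interferon-induced genes were higher in 5 of 19 transcripts (13 adjusted over the list alone; median 1.45; adjusted p = 2.42e-14, and adjusted p = 0.0128 with an estimated correlation). Here 1 of 2 irf1b transcripts averaged 86.1 ± 36.3 against 11.5 ± 7.45 CPM (7.45-fold, adjusted p = 0.000399; gene value 1.12), and ifit9, mx2 and mx were 17.1-fold, 3.93-fold and 3.74-fold higher. MHC class I presentation was higher in 4 of 9 (6 adjusted over the list alone; median 0.35; adjusted p = 6.42e-09, and adjusted p = 0.0141 with an estimated correlation). The transporter tap1 was at 139 ± 23.1 against 89.5 ± 10.9 CPM (1.55-fold, adjusted p = 0.00648). The chaperone tapbpl and the proteasome subunits psmb9a and psmb8a were 2.56-fold, 1.62-fold and 1.55-fold higher. Liver-secreted proteins were lower in Select in 1 of 4 (2 adjusted over the list alone; median -1.53; adjusted p = 0.000116, and adjusted p = 0.0128 with an estimated correlation). It was the plasma protein ambp, at 1.33 ± 1.1 against 8.97 ± 2.47 CPM (6.64-fold, adjusted p = 0.0129). The liver glycogen synthase gys2 was 23.9-fold lower (0.174 ± 0.0745 against 4.49 ± 1.64 CPM, adjusted p = 0.000663), cyp1a3 10.6-fold lower (adjusted p = 0.012, 5 of 6 pools) and pkd1l2a 6.82-fold lower (gene value -1.63). Fatty acid oxidation had 3 of 24 lower (8 adjusted over the list alone; adjusted p = 0.000913, but adjusted p = 0.116 with an estimated correlation). Complement, with cfh 3.08-fold higher, had 1 of 10 called (2 adjusted over the list alone; adjusted p = 0.325 with an estimated correlation). T cell markers had 1 of 13 (2 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation). Cytokines (adjusted p = 0.213 with an estimated correlation) and skeletal muscle (0.178) were higher and the goblet cell list (0.187) and enteroendocrine genes (0.155) lower with the preset correlation only. Of the largest differences, transcripts of hnrnpa1a, ddx24, dhrs7, gatad2ab and tnr5 were at least 433-fold, 313-fold, 218-fold, 118-fold and 68.8-fold higher in Select, and 1 of bxdc2 at least 76.7-fold lower. The genes hnrnpa1a, ddx24, gatad2ab and bxdc2 had values of 0.56, 0.20, 0.33 and 0.03, and dhrs7 and tnr5 had no other transcript to sum. Transcripts of baz1a and cd4-1 were 31.6-fold and 20.6-fold higher, or 9.93 and 8.21 on the log2 scale without TF2-2 and TF3-1 in place of 4.98 and 4.37, and the gene value of cd4-1 was -0.08. All 6 Select pools lay beyond every Commercial pool for each named transcript except gatad2ab and mx (4 of 6), psmb8a and cyp1a3 (5 of 6). By edgeR, 362 transcripts were higher and 361 lower, 129 of them with a symbol, and 6509 had an unadjusted p under 0.05. The count was 429 without TF2-2, 456 without CF2-1, 469 without CF3-1 and 459 without CF3-2. Of the 21 named calls, those of ddx24, dhrs7, tnr5, irf1b, tap1, psmb8a, psmb9a, bxdc2, gys2, cyp1a3 and ambp held in every fit. The losses were 8 without TF1-1, 6 without TF1-2, 7 without TF2-1, 9 without TF2-2, 7 without TF3-1, 10 without TF3-2, 5 without CF1-1, 1 without CF1-2, 5 without CF2-1, 5 without CF2-2, 7 without CF3-1 and 8 without CF3-2 (adjusted p 0.0501 to 0.127). Summing the pools of a tank left 75 calls, and libraries with a bias score above 0, with TF1-2 as the only Commercial infected pool, gave 43, and those below 0 gave 566.

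**Figure D4:**
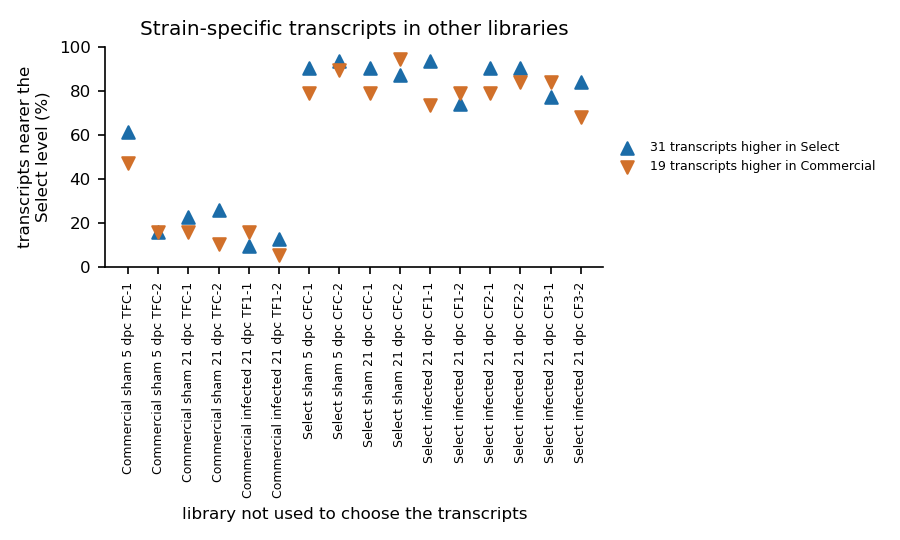
Share (y axis, percent) of transcripts that differ at least 32-fold between the strains and stand nearer the Select level, for each library (x axis). The 50 transcripts were chosen in the infected pools of 5 dpc, and only libraries not used for that choice are drawn. Each library has 1 point for the 31 transcripts higher in Select and 1 for the 19 higher in Commercial. TFC-1 of 5 dpc lies at 61.3% and 47.4%.

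Infected fish of the strains were also compared at 21 dpc, with 6 Select pools against the 2 Commercial pools of TF1. Serum amyloid A was 19.4-fold lower in Select (17.1 ± 15.8 against 337 ± 240 CPM, adjusted p = 0.00204), and prf1.3 8.23-fold (7.07 ± 3.64 against 58.4 ± 11.4 CPM, adjusted p = 0.00204). Also lower were cxcl13 10.6-fold, acod1 6.43-fold (adjusted p = 0.0044), lyz2 3.82-fold (adjusted p = 0.00497), cd79b 4.23-fold (adjusted p = 0.00388) and the interleukin receptor il6r 2.92-fold (adjusted p = 0.005). The glycogen synthase gys2 was 7.4-fold lower, the globin hba1 5.37-fold higher and ggt1b 1.77-fold higher. No list was called with an estimated correlation. Acute phase proteins (2 of 5 down, 2 adjusted over the list alone) were lower with the preset correlation (adjusted p = 0.00628, but adjusted p = 0.0804 with an estimated correlation). The same held for neutrophil markers (1 of 13 down, 3 adjusted over the list alone; adjusted p = 0.0804 with an estimated correlation), B cell markers (1 of 7 down, 2 adjusted over the list alone; adjusted p = 0.0586 with an estimated correlation), macrophage markers (adjusted p = 0.0869 with an estimated correlation) and cytokines (0.144). Erythrocyte genes (1 of 7 up, 4 adjusted over the list alone; adjusted p = 0.0593 with an estimated correlation), brush border genes (0.0898), fatty acid oxidation (0.108) and cholesterol biosynthesis (0.266) were higher. Transcripts of ddx24, dhrs7, mdp1, znf740b, tnr5, pfkfb2a and mtss1lb were at least 213-fold, 89.2-fold, 38.4-fold, 26.6-fold, 24.7-fold, 19.8-fold and 19-fold higher, that of appa at least 114-fold lower and that of bxdc2 61.1-fold lower. The genes mdp1, ddx24, znf740b, pfkfb2a, mtss1lb, appa and bxdc2 had values of 3.30, 0.46, -0.22, -0.07, -0.43, 0.15 and 0.42, and dhrs7 and tnr5 had no other transcript to sum. Of the named transcripts, all lay beyond both Commercial pools in all 6 Select pools except znf740b and mtss1lb (5 of 6) and bxdc2 (0 of 6), which had 0 counts in TF1-1. By edgeR, 237 were higher and 533 lower, 134 of them with a symbol, and 6142 had an unadjusted p under 0.05. None of the 19 named calls held in every fit: 18 were lost without TF1-1 (adjusted p 0.0907 to 0.492), 11 without TF1-2 (0.0661 to 0.72, with bxdc2 at 2.89 in place of -5.93), and 6 without CF1-2, 4 without CF2-1, 6 without CF2-2, 6 without CF3-1 and 2 without CF3-2 (0.0509 to 0.0765). The total was 69 without TF1-1, 2000 without CF1-1, 501 without CF1-2, 491 without CF2-2, 482 without CF3-1, 265 without tank CF2 and 231 among libraries with a bias score above 0.

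Sham fish of the strains, 2 pools each, differed in 7 transcripts up and 7 down at 5 dpc (2523 with an unadjusted p under 0.05) and in 20 up and 13 down at 21 dpc (2378). At 5 dpc the only symbol was itcha, at least 17.5-fold higher in Select (adjusted p = 0.0317; gene value 1.06), lost without TFC-1 (0.163), TFC-2 (0.259) or CFC-1 (0.143), and the count was 67 without TFC-1, 39 without TFC-2 and 41 without CFC-2. At 21 dpc the oxidoreductase dhrs7 was at least 128-fold higher in Select (25.1 ± 6.04 CPM against 0, adjusted p = 0.021), a call lost without TFC-1 (0.133) or TFC-2 (0.149), and tmm85, malt2 and c1h19orf44 were at least 75.4-fold, 26.2-fold and 16.7-fold higher with gene values of 0.46, -0.08 and 0.07, calls that held without any 1 of the 4 pools. The other symbol was grpel2, 3.4-fold higher (17.4 ± 3.08 against 5.1 ± 0.585 CPM, adjusted p = 0.0198), a call lost without TFC-1 (0.192), TFC-2 (0.117) or CFC-2 (0.22). The count was 60 without TFC-1 and 60 without TFC-2. With the preset correlation alone, the unfolded protein response was lower at 5 dpc (adjusted p = 0.748 with an estimated correlation). At 21 dpc exocrine pancreas enzymes and cholesterol biosynthesis were higher and heat shock proteins lower (adjusted p = 0.687 to 0.752 with an estimated correlation).

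Time after infection was compared within Select fish, 6 pools at 21 dpc against 6 at 5 dpc. Interferon-induced genes, cytokines and chemokines were lower at 21 dpc, and a number of cell division, protein folding and lipid transcripts were higher. The chemokine ccl19a.1 fell 61.7-fold from 305 ± 61.4 to 4.69 ± 5.72 CPM (adjusted p = 2.85e-07), the transcription factor batf2 41.8-fold to 0.543 ± 0.412 CPM (adjusted p = 3.91e-07), and the hormone fgf21, helz2a and ifit9 fell 55.0-fold, 45.6-fold and 43.5-fold, with a gene value of -2.23 for helz2a. Interferon-induced genes fell in 14 of 19 (17 adjusted over the list alone; median -2.91; adjusted p = 4.56e-11, and adjusted p = 0.0344 with an estimated correlation). Here irf1b fell 17.8-fold (adjusted p = 4.82e-07), the antiviral vig1 at least 44.8-fold and 1 stat1b transcript at least 24.8-fold (gene value -3.23). Cytokines and chemokines fell in 9 of 16 (11 adjusted over the list alone; median -1.35; adjusted p = 3.48e-05, and adjusted p = 0.0344 with an estimated correlation), with il10 at a ratio of 29.9 (7.95 to 252). Complement had 7 of 10 down (8 adjusted over the list alone; adjusted p = 0.0824 with an estimated correlation), c7b by 19.1-fold (adjusted p = 2.13e-07) and cfh by 5.92-fold. MHC class I presentation had 5 of 9 down (7 adjusted over the list alone; adjusted p = 0.0645 with an estimated correlation), tap1 by 3.33-fold to 41.7 ± 6.35 CPM (adjusted p = 5.46e-09). Fatty acid oxidation had 11 of 24 up and 2 down (14 and 3 adjusted over the list alone; adjusted p = 0.0645 with an estimated correlation), with acsl4a and acadvl 2.85-fold and 2.73-fold higher. Cell division had 8 of 16 up (8 up and 1 down adjusted over the list alone; adjusted p = 0.166 with an estimated correlation), with mcm5 2.72-fold and aurka 2.43-fold higher. The unfolded protein response had 8 of 16 up and 1 down (10 and 1 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), with the chaperones calr 4.97-fold and dnajc3a 3.53-fold higher. Cholesterol biosynthesis had 10 of 22 up and 1 down (10 and 1 adjusted over the list alone; adjusted p = 0.596 with an estimated correlation), with 2 transcripts of idi1 4.05-fold and 3.15-fold and mvda 3.46-fold higher. Extracellular matrix had 8 of 10 down (8 adjusted over the list alone; adjusted p = 0.166 with an estimated correlation), sparc by 2.12-fold and loxl4 at a ratio of 53.4 (9.21 to 2140). Single transcripts of nup153, trip12 and rasal2 were at least 174-fold, 142-fold and 42.6-fold lower, and those of ttll5 and kansl1a at least 314-fold and 84.1-fold higher. The gene values of the last 4 were -0.53, -0.17, 0.61 and -0.29, and nup153 had no other transcript to sum. All 6 pools of 21 dpc lay beyond every pool of 5 dpc for each named transcript except mcm5, idi1, mvda and ttll5 (5 of 6), aurka (4), kansl1a (3), and nup153, trip12, rasal2 and stat1b (0), which also lacked counts in at least 1 pool of 5 dpc. By edgeR, 5607 transcripts were higher and 5823 lower, 2274 of them with a symbol, and 16452 had an unadjusted p under 0.05. Of the 28 named calls, that of trip12 was lost (adjusted p 0.0574 to 0.0671) without any 1 pool of 21 dpc or without CF1-1, CF1-2 or CF2-2 of 5 dpc, that of kansl1a (0.0505) without CF1-2 of 21 dpc, and the other 26 held. Without CF2-1 and CF3-2, in which helz2a and ifit9 of 21 dpc had their counts, these stood at -11.81 and -11.59 in place of -5.51 and -5.44. Libraries with a bias score above 0 gave 3263 calls, those below 0 8704, and pools of a tank summed 7067.

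In Commercial infected fish the 2 pools of 21 dpc (tank TF1) were set against 6 pools of 5 dpc, and T and B cell transcripts were higher. T cell markers rose in 4 of 13 (7 adjusted over the list alone; median 0.80; adjusted p = 0.000124, and adjusted p = 0.0261 with an estimated correlation). The transcription factor tbx21 was at 4.0 ± 0.591 against 0.257 ± 0.114 CPM (14.6-fold, adjusted p = 0.00356). The receptor subunit cd3e rose 2.16-fold and 1 cd4-1 transcript 45.5-fold (gene value 0.64). B cell markers rose in 1 of 7 (1 adjusted over the list alone; median 1.44; adjusted p = 0.00342, and adjusted p = 0.0355 with an estimated correlation). Receptor subunit cd79b was at 17.2 ± 4.3 against 1.96 ± 0.599 CPM (8.74-fold, adjusted p = 5.34e-05). Perforin (prf1.3) rose 30.4-fold from 1.9 ± 0.515 to 58.4 ± 11.4 CPM (adjusted p = 2.26e-05) and hce23 9.85-fold. Neutrophil markers had 3 of 13 up (4 adjusted over the list alone; adjusted p = 0.185 with an estimated correlation), csf3r by 8.05-fold (gene value 1.44) and il6r by 3.89-fold (adjusted p = 0.000305). Enteroendocrine hormones had 2 of 8 down (2 adjusted over the list alone; adjusted p = 0.0622 with an estimated correlation), gcg2 by 2.26-fold from 56.3 ± 7.6 to 25 ± 3.87 CPM (adjusted p = 0.000833) and insl5a by 2.09-fold. Complement had 2 of 10 down (2 adjusted over the list alone; adjusted p = 0.289 with an estimated correlation), c7b by 6.21-fold. Erythrocyte genes had 1 of 7 down (4 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation), hba1 by 5.59-fold. Extracellular matrix had 3 of 10 down (5 adjusted over the list alone; adjusted p = 0.0753 with an estimated correlation), sparc by 2.51-fold and col1a1 by 2.41-fold. The unfolded protein response had 3 of 16 up (4 adjusted over the list alone; adjusted p = 0.361 with an estimated correlation), with calr 2.66-fold and dnajc3a 2.41-fold higher. The goblet cell list (adjusted p = 0.0753 with an estimated correlation), interferon-induced genes (0.241) and brush border genes (0.268) were lower and cell division (0.203) higher with the preset correlation only. Of cblnl, 2 transcripts fell 12.9-fold and 9.99-fold. Single transcripts of znf740b, mtss1lb, capn1 and pfkfb2a were at least 33.9-fold, 33.9-fold, 31.4-fold and 22-fold lower, with gene values of 0.02, -0.20, -0.81 and 0.16. Both pools of 21 dpc lay beyond every pool of 5 dpc for each named transcript except znf740b and pfkfb2a, which also lacked counts in at least 1 pool of 5 dpc. By edgeR, 1034 were higher and 1119 lower, 361 of them with a symbol, and 8331 had an unadjusted p under 0.05. The total was 474 without TF1-1 and 920 without TF1-2, and of the 22 named calls 14 were lost in each (adjusted p 0.0653 to 0.381 and 0.0565 to 0.256), with c7b at -4.45 and hce23 at 1.80 without TF1-1 in place of -2.63 and 3.30. Without TF3-1 of 5 dpc cd4-1 stood at 9.35 in place of 5.51, and each pool of 5 dpc left out ended 1 to 3 calls (0.0507 to 0.0628). The calls of prf1.3, cd79b, il6r, tbx21, gcg2 and 1 cblnl transcript held in every fit. With tank as replicate block 15 were called, with pools of a tank summed 255, with the bias score as covariate 1352, and among libraries with a score above 0, with TF1-2 as the only pool of 5 dpc, 172.

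Sham fish of 21 and 5 dpc, 2 pools each, differed in 4 transcripts up and 2 down in Select (2636 with an unadjusted p under 0.05, none with a symbol) and in 20 up and 17 down in Commercial (3814). In Commercial sham fish tmm85 and malt2 were at least 98.4-fold and 17-fold lower at 21 dpc, calls that held without any 1 of the 4 pools, and itcha at least 10.4-fold higher, a call lost without any of the 4 pools (TFC-1 and TFC-2 of each day; adjusted p 0.0554 to 0.251). Their gene values were -0.54, 0.06 and 0.75. Extracellular matrix genes were lower in both strains with the preset correlation (adjusted p = 0.119 in Select and 0.313 in Commercial with an estimated correlation). In Commercial sham fish complement, smooth muscle, skeletal muscle, erythrocyte, cell division, unfolded protein response, cholesterol biosynthesis and fatty acid oxidation genes were also lower and interferon-induced and MHC class I genes higher with the preset correlation only (adjusted p = 0.313 or 0.479 with an estimated correlation). Leaving out 1 library gave more calls in Select: 29 and 19 without CFC-1 and CFC-2 of 21 dpc, and 19 and 17 without those of 5 dpc. In Commercial the counts were 67 and 75 without TFC-1 and TFC-2 of 21 dpc and 81 without TFC-1 of 5 dpc.

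Whether the response of Select fish changed between the days was tested as time by infection, the response at 21 dpc minus that at 5 dpc. Interferon and antigen presentation genes responded less at 21 dpc and fatty acid oxidation genes had a higher response. Interferon-induced genes were lower in 5 of 19 (13 adjusted over the list alone; median -2.56; adjusted p = 3.76e-12, and adjusted p = 0.0185 with an estimated correlation). Here 2 irf1b transcripts stood at log2 -3.56 and -3.38 and dhx58 at -3.37 (adjusted p = 0.0074). MHC class I presentation was lower in 3 of 9 (6 adjusted over the list alone; median -0.85; adjusted p = 3e-08, and adjusted p = 0.0185 with an estimated correlation). Transporter tap1 stood at -1.79 ± 0.241 SE (adjusted p = 0.000549) and psmb8a at -0.94. Fatty acid oxidation was higher in 7 of 24 (12 adjusted over the list alone; median 1.09; adjusted p = 2.9e-07, and adjusted p = 0.0185 with an estimated correlation). The carnitine carrier slc25a20 stood at 1.83. Brush border genes had 4 of 16 higher and 1 lower (6 and 2 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation). The carrier fabp2 stood at 2.38 ± 0.378 SE (adjusted p = 0.00214), vil1 at 1.39 and anpepa at 1.29. Complement (c7b at -3.93; 1 of 10 lower, 2 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation) and cytokines (1 of 16 lower, 1 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation) were lower with the preset correlation. Cell division (top2a at 1.69; 1 of 16 higher, 7 adjusted over the list alone; adjusted p = 0.111 with an estimated correlation), the unfolded protein response (adjusted p = 0.796) and cholesterol biosynthesis (adjusted p = 0.469 with an estimated correlation) were higher. Other transcripts with a higher response were prf1.3 (4.17, adjusted p = 0.0158), pkd1l2a (4.88), gata6 (3.16, gene value 1.13), pla2g12b (3.0), the fatty acid desaturase fd6d (2.71) and plvapb (2.70). Those with a lower one were ccl19a.1 (-6.04) and batf2 (-5.52). Single transcripts of cdk2ap2, si:dkey-220k22.1, nmd3, si:ch211-148l7.4 and dusp12 stood at 9.70, 6.13, -9.44, -8.01 and -6.58, with gene values of 0.66, -0.01, -0.30, -1.46 and 0.37. By edgeR, 722 were higher and 620 lower, 320 of them with a symbol, and 7396 had an unadjusted p under 0.05. The count was 153 without CFC-2 of 5 dpc, 228 and 493 without CFC-1 and CFC-2 of 21 dpc, and 3010 without CF1-1 of 21 dpc. Of the 24 named calls those of tap1 and fabp2 held in every fit. Without sham pools CFC-1 and CFC-2 of 5 dpc 7 (adjusted p 0.0583 to 0.149) and 22 (0.0808 to 0.38) were lost, and without those of 21 dpc 21 (0.0599 to 0.275) and 16 (0.0501 to 0.21), the last with gata6 at 5.52 in place of 3.16. Without infected pools of 21 dpc the losses were 2 (CF1-2), 3 (CF2-1), 3 (CF2-2), 4 (CF3-1) and 2 (CF3-2), and without those of 5 dpc 1 (CF1-1), 5 (CF2-1), 3 (CF2-2), 3 (CF3-1) and 3 (CF3-2), with adjusted p from 0.0508 to 0.0654. Pools of a tank summed left 78 calls, and libraries with a bias score above 0, with CFC-1 as the only sham pool of 5 dpc, left 38.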

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

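In this part, the tests of 1 library and of a late stage in Commercial fish at 21 dpc, and those of reads moving between transcripts, of a mislabelled sample and of a pool of both strains, were chosen only after the result was seen, as was the use of the bias score's sign; the tests of 1 library and of a mislabelled sample replace earlier forms, the first for 1 library being void as it used transcripts called from the same pools, and the reverse choice was added after the first values of the new form were seen.

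The 2960 transcripts called between infected and sham Select fish at 5 dpc could come from differences between libraries or tanks. With the library bias score as a covariate 81.9% of them kept their direction and passed, and their median log2 fold change was 101.3% of that without it, which argues against library bias as the whole cause. Without any 1 infected tank at least 1974 were called, which argues against a single infected tank. Comparisons of 2 infected tanks called 3 transcripts on average, and those of an infected tank with the sham tank 1534.3, which argues against differences of the size seen between infected tanks. A peculiarity of the only sham tank stays open beside a response to infection, since the design has no second sham tank.

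The 715 transcripts called in Commercial fish at 21 dpc rest on 2 infected pools of 1 tank. Their median log2 change was 2.09 in TF1-1 and 1.58 in TF1-2, the pools that chose them. Transcripts chosen from TF1-1 and 1 sham pool had in TF1-2, against the other sham pool, 37.9% and 40.1% of their median change in TF1-1. This was under the bar of 50% set for 1 library as the source. The reverse choice gave 6.3% and 36.6%, so choosing alone may lower such values. Whether TF1-1 is the source cannot be told with 2 pools. A candidate explanation is a late stage of the response of 5 dpc: transcripts that rose or fell in both strains at 5 dpc had medians of 0.45 and -0.20 here (camera p = 4.66e-26 and 8.06e-12 with the preset correlation, p = 0.00974 and 0.115 with an estimated correlation). The same sets had medians of 0.11 and -0.04 in Select fish at 21 dpc (p = 0.487 and 0.642 with an estimated correlation), -0.39 and 0.21 in the interaction (p = 0.0352 and 0.228) and 0.15 and -0.35 between the days in Commercial sham fish (p = 0.273 and 0.0845, or 3.78e-05 and 4.22e-14 with the preset correlation). Differences of tank TF1, or of fish that survived, stay open and untested.

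Of the transcripts that differed at least 32-fold between the strains, many may reflect reads assigned to another transcript of the same gene, or a strain variant against the reference, not tested. Among those whose gene has other transcripts, the summed gene differed by under 2-fold for 11 of 18 (61.1%) chosen at 5 dpc. For those chosen at 21 dpc it did so for 16 of 21 (76.2%), and a transcript can be in both sets. In the Commercial sham pool TFC-1 of 5 dpc, 56% of the 50 transcripts chosen at 5 dpc were nearer the Select level, with 10% to 20% in the other Commercial pools and 76% or more in Select pools, and 71.9% of the 57 chosen at 21 dpc, with 38.6% to 54.4% in the other Commercial pools and 71.9% in the lowest Select pool. The second component score of TFC-1 was -48.9, which lay 63.7 below the lowest Select pool, where Select pools had an SD of 22.5. This argues against a pool of Select fish alone. The score lay above the other Commercial sham pools (-100.5 to -91.1) but within the range of the Commercial infected pools of 5 dpc (-62.6 to -45.2). For a pool of both strains, 47.4% and 50% of transcripts higher in Commercial were nearer the Select level there, between the strains in both sets (at most 15.8% and 41.7% in other Commercial pools, at least 68.4% and 54.2% in Select), but for transcripts higher in Select 61.3% lay between and 87.9% within the Select range. Such a pool stays open, as do Commercial fish that share variants with Select, not tested, and strain comparisons of sham fish at 5 dpc and the response of Commercial fish at 5 dpc rest in part on this pool.

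Splits of the samples were drawn for both comparisons of 6 against 6 pools, 100 of 462 each, in models of these libraries alone. Between the strains in infected fish at 5 dpc the real split called 793 and the highest other 3. The real split was the only 1 of the 100 as large, which argues against a random grouping of pools. Single pools were exchanged and each tank held 1 strain, so these splits cannot separate strains from tanks. Between 21 and 5 dpc in infected Select fish the real split called 10364 and the highest other 6406. Again the real split was the only 1 of the 100 as large, which argues against a random grouping of pools. The splits left out of account that the same tanks were sampled on both days. The split with 6406 exchanged 1 library per side, as did 7 of those drawn. Splits that exchanged another number called at most 5, which points to the structure of these samples by day.

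In 9 of 96 measures a library stood far from the others of its group, where chance gives about 1 in 20. Among Select infected pools of 5 dpc, CF3-2 had a total of 8.99 (in units of 1000000 counts; others 6.91 to 7.58) and a mean log2 CPM of heat shock proteins of 3.53 (3.22 to 3.33), CF1-2 a second component score of 38.7 (68.5 to 83.7) and macrophage markers at 4.29 (5.92 to 6.65), and CF2-1 T cell markers at 1.04 (1.36 to 1.51). Among Select infected pools of 21 dpc, CF1-1 had a TMM factor of 1.097 (0.944 to 1) and agr2, the goblet cell list, at 5.94 (6.93 to 7.51). Among Commercial infected pools of 5 dpc, TF3-1 had B cell markers at 0.54 (0.954 to 1.199) and TF3-2 extracellular matrix genes at 5.72 (4.63 to 4.79). Differences between groups by a test of the difference itself were the 8 and 10 transcripts of the strain by infection interaction at 5 and 21 dpc and the 1342 of time by infection in Select fish.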

How the results depend on the processing

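The fits with a bias score were chosen only after the data were seen, while the other alternatives were planned; the cause was not tested where a value moved, except that summed pools, single groups and subsets of libraries hold fewer samples. DESeq2 called 5483 and 5533 transcripts for infection at 5 dpc in Select and Commercial fish, 2075 and 2207 at 21 dpc, 194 and 346 for the interaction at 5 and 21 dpc, 1898 and 2427 between infected strains, 346 and 384 between sham strains, 4691 over time in infected Commercial fish, 317 and 724 in Select and Commercial sham fish, and 3610 for time by infection. Limma-voom with tank as a random block called 5269 and 495 for infection in Select fish at 5 and 21 dpc, 17 and 19 for the interactions, 63 between sham strains at 5 dpc, 1547 between infected strains at 21 dpc, 3464 over time in infected Commercial and 44 in Select sham fish. With pools of a tank summed there were 695 and 1 calls for infection in Select, 629 and 200 in Commercial, 25 and 5 for the interactions, 75 and 126 between infected strains, 31 between sham strains at 5 dpc, 7067 and 255 over time in infected Select and Commercial fish, 17 in Select sham fish and 78 for time by infection. Libraries with a bias score above 0, with 1 pool left of Commercial infected (TF1-2) and of Select sham fish (CFC-1) at 5 dpc, gave 353 and 3 for infection in Select, 522 in Commercial at 5 dpc, 26 for the interaction at 5 dpc, 43 and 231 between infected strains, 39 between sham strains at 5 dpc, 3263 and 172 over time in infected Select and Commercial fish, 16 in Select sham fish and 38 for time by infection. Those below 0 gave 2410 for infection in Select and 566 between infected strains at 5 dpc and 8704 over time in infected Select fish. The score as covariate moved infection in Select at 21 dpc to 10, infected strains at 21 dpc to 470 and infected Commercial fish over time to 1352. With an absolute log2 fold change of at least 1 there were 1717 and 1785 for infection at 5 dpc in Select and Commercial, 399 between infected strains at 5 dpc, and 5139 and 1301 over time in infected Select and Commercial fish. For Select at 21 dpc, no filter gave 7 and a filter of 1 CPM in 6 libraries 71. Fitting only the groups compared gave 13 for Select at 21 dpc, 20 and 18 for the interactions, 49 between infected strains at 21 dpc and 737 for time by infection. In that setting edgeR called 0 for Commercial infection at 21 dpc (4039 with an unadjusted p under 0.05; 2207 by DESeq2 fitted to all groups, as in the following pairs), sham strains at 5 dpc (1935; 346) and 21 dpc (2723; 384), and sham fish over time in Select (2543; 317) and Commercial (3339; 724). Genes in place of transcripts gave 565 for Select at 21 dpc, 3 for the interaction at 21 dpc, 5 and 12 between sham strains, 19 over time in Commercial sham fish and 2064 for time by infection, and edgeR called 0 genes for the interaction at 5 dpc (1041 with an unadjusted p under 0.05; 194 transcripts by DESeq2) and Select sham fish over time (1569; 317).

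Summing by gene turned the sign of 22 named values. These were cd4-1 (0.86), c1h19orf44 (-0.82) and mtss1lb (0.24) in Commercial infection, c1h19orf44 (0.45) in the interaction at 21 dpc, cd4-1 (-0.084) and bxdc2 (0.031) between infected strains at 5 dpc, znf740b (-0.22), pfkfb2a (-0.067), mtss1lb (-0.43), appa (0.15) and bxdc2 (0.42) at 21 dpc, and malt2 (-0.075) between sham strains. Over time they were kansl1a (-0.29), nfat5a (-0.009) and zgc:101583 (-0.95) in infected Select, znf740b (0.022) and pfkfb2a (0.16) in infected Commercial and malt2 (0.06), c1h19orf44 (0.32) and capn1 (0.30) in Commercial sham fish, and si:dkey-220k22.1 (-0.007) and dusp12 (0.37) in time by infection. Between infected strains at 21 dpc bxdc2 ran from -8.84 without tank CF3 to 2.89 without TF1-2. Of the other named values, bias scores above 0 ended 236 calls and those below 0 47 (92 stayed on their side of the threshold), summed pools 194, only the groups compared 113, limma-voom 95, the bias covariate 57, no filter 49, tank as block 37 (37 stayed), genes 32, a log2 fold change of at least 1 22, pool number as block 12, the effective length offset 8, DESeq2 2 (12 added) and RLE scaling 1. Without 1 library or tank, 928 pairs of a named transcript and a fit lost the call and 3918 kept their side. Of the list results, 106 calls were lost with an estimated correlation and 21 with summed pools, which added 8.

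Leaving out 1 library gave 688 to 3158 calls for infection in Select at 5 dpc and 4 to 2098 at 21 dpc, 522 to 3226 in Commercial at 5 dpc and 163 to 777 at 21 dpc, 7 to 46 and 10 to 87 for the interactions, 429 to 816 and 69 to 2000 between infected strains, 21 to 67 and 25 to 60 between sham strains, 10052 to 12792 and 474 to 2107 over time in infected Select and Commercial, 17 to 29 and 54 to 81 in sham fish, and 153 to 3010 for time by infection. Leaving out 1 infected tank gave 1974 to 3180 and 2 to 2365 for infection in Select at 5 and 21 dpc, 1971 to 2714 in Commercial at 5 dpc, 278 to 701 and 265 to 1685 between infected strains and 8482 to 11967 over time in Select.

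Pool numbers do not pair the libraries, since deviations of pools with the same number in different groups had a mean correlation of 0.004; with pool number as replicate block Select infection at 21 dpc gave 148 calls. With tank as replicate block infected Commercial fish over time gave 15. That block could not be fitted for contrasts of infected with sham fish, in which each tank has 1 treatment.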

Other observations

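No test of an explanation was added in this part; the transcripts named here meet the rule for named genes and were singled out after their values were seen because each call held without any 1 library.

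Several secreted and signalling genes that no list holds, or that stand lower in a list, also differed. The chemokine ccl25a (XM_021614083.1) rose 2.9-fold in Select fish at 5 dpc. It rose 3.31-fold in Commercial fish of that day, from 227 ± 11.4 (SD, n = 2) to 753 ± 99 CPM (n = 6; adjusted p = 0.00037 by edgeR, all 6 pools above both sham pools). The plasmin inhibitor serpinf2b fell 11.3-fold there (adjusted p = 0.000116, all 6 pools). The ependymin-like gene epdl2 fell 5.32-fold in Select fish at 5 dpc, from 1648 ± 283 to 310 ± 116 CPM (adjusted p = 0.00209, all 6 pools), and was 3.4-fold lower in infected Select than in infected Commercial fish of that day (1053 ± 137 CPM in the latter; adjusted p = 0.0137, all 6 pools). The nucleotide hydrolase dnph1 fell 5.41-fold in Select fish at 5 dpc (adjusted p = 0.000103, all 6 pools). The connexin gja13.2, a gap junction protein, was 4.49-fold lower in infected Select than in infected Commercial fish at 5 dpc (22.9 ± 5.35 against 103 ± 33.3 CPM, adjusted p = 0.0108, all 6 pools).

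In infected Select fish the cytokine il11 was 7.73-fold lower at 21 than at 5 dpc (adjusted p = 0.0132, all 6 pools) and the chemokine ccl4 4.69-fold lower (adjusted p = 0.00796, all 6 pools), while fdps, an enzyme of the mevalonate pathway, was 3.25-fold higher (adjusted p = 0.00149, 5 of 6 pools). In Commercial fish at 21 dpc the chemokine-like cxcf1b had no sham count and was at least 13.5-fold higher (adjusted p = 0.00149, both pools).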
